A study of Rattus norvegicus with 9 samples.

How the data were processed

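RNA of the renal outer medulla was sequenced in 9 rats of the salt-sensitive strain MCW SS, 3 rats in each of 3 groups, with 1 library per rat. Per the labels, RNA was extracted with Trizol and libraries were prepared on an Illumina NeoPrep system, and the descriptions of all 9 libraries end in the same lane code. The deposited values are FPKM (fragments normalised to transcript length and to the number of mapped fragments), computed by the authors at 30315 loci. Trim Galore 0.2.5, Cufflinks 2.2.1 and the rat genome build rn5 are named per the submitters' processing notes. The aligner, the gene annotation and any scaling between libraries are not given in the sources used here. Each library was matched to its column by the rat number in its title. A further column with the number of HS_DT replicate 3 repeats its values at all 30315 loci and was not used.

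Of the loci, 4095 have no gene name, 5531 carry an Ensembl identifier only and 550 carry several names. Positions are those of the table, on build rn5. Where several loci share a name, a gene list takes the locus with the highest mean FPKM.

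Read counts and the number of mapped fragments are not given in the sources used here, so the depth of each library is unknown and no counting interval is given. A relative depth was estimated from loci with a mean under 0.15 FPKM, where single fragments set the values. Between 81.1% and 85.9% of the ratios of such values between libraries lay within 2% of a ratio given by whole numbers up to 6, against 28.5% when the factor was random. With 0.4% salt replicate 1 set to 1, the relative depth ran from 0.761 in HS_SCR replicate 2 to 1.37 in HS_DT replicate 2. The sum of FPKM per library ran from 685349 in 0.4% salt replicate 3 to 933862 in HS_SCR replicate 2.

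Values were analysed as log2(FPKM + 1) at the 14338 loci with a mean of at least 1 FPKM over the 9 libraries, of which 11721 have a single gene symbol. Changes were tested with limma 3.58.1 in R 4.3.3, with variance moderation that follows the mean level (limma-trend), in a single fit of the 3 groups with 6 residual degrees of freedom (8.54 after moderation). The tests were two-sided, p was adjusted by Benjamini-Hochberg over the tested loci of a comparison, and loci under an adjusted p of 0.05 are called changed. The comparisons were HS_SCR minus 0.4% salt, HS_DT minus HS_SCR and HS_DT minus 0.4% salt, with a moderated F test over the 3 groups. Log2 changes are given with their standard error (SE) and group means with their standard deviation (SD), n = 3. For Dnmt3a and Tet3 an exact two-sided permutation test of 3 against 3 libraries was added, whose smallest possible p is 0.1.

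Gene lists for pathways, cell types and complexes of the kidney were written from general knowledge. Of the 33 lists, 31 had at least 5 tested members; the lists of distal convoluted tubule markers and of mitochondrially encoded genes, with 4 tested members each, were not tested. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 31 lists. Camera compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether the members of a list move on balance in a common direction, were run as alternatives. Members of lists are called over all genes tested, and counts adjusted over the list alone are named as such.

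Named genes follow a rule: Dnmt3a and Tet3; in each direction, the 10 single-symbol genes with the largest change among those called changed with FPKM ranges that do not overlap; where fewer passed, the smallest unadjusted p fills the 10, given as values that did not pass. From each list, up to 4 called members with the largest change are named, or the 2 with the smallest unadjusted p where none was called. Genes with both means under 1 FPKM are not named, and some genes that the rule selects are not reported here. The groups, the tests, the gene lists, the naming rule and the alternatives were fixed before the data were examined, except 3 alternatives chosen after seeing the data: the proximal tubule score of each library (the mean log2 value of the proximal tubule markers) as a covariate, removal of the trend of each library on locus width (lowess, span 0.3), and leaving out the 2 libraries with the highest proximal tubule score of their groups (0.4% salt replicate 2 and HS_DT replicate 3).

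The other alternatives were pseudocounts of 0.1 and 0.5 FPKM, no filter and a minimum mean of 5 FPKM, median-ratio rescaling, quantile normalization, robust moderation, library weights, a fit of the 2 groups compared only, the replicate number as a block, the series of the rat number as a factor, and leaving out each library in turn. The replicate numbers are not said to pair rats, so the libraries were treated as unpaired in the main fit. Across genes, residuals of libraries with the same number correlated above 0.1 in 5 of 9 pairs, with correlations from -0.08 to 0.26. Pairs with different numbers ran from -0.31 to 0.24. Of the libraries, 5 of 9 correlated best with a library of their own number, so these values do not exclude a pairing.

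The procedure was tested on simulated data with 200 changed genes among 14338. It recovered 79%, 83% and 84% of 2-fold changes and 99%, 98% and 97% of 4-fold changes in the 3 comparisons, with 16, 12 and 10 false calls, and called the 1 list that was moved out of 31. The simulated genes varied independently of each other, with equal spread in all libraries. These rates need not hold for the real libraries or for lists whose members vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.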

Results

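RNA of the renal outer medulla, the zone that holds the thick ascending limbs and the last part of the proximal tubule, was measured in 9 salt-sensitive rats, each giving 1 library. The 3 rats labelled 0.4% salt had the same surgery as the others and were collected before GapmeR or high-salt diet would have begun. The 3 rats labelled HS_SCR received a scrambled GapmeR, an antisense oligonucleotide with no intended target, into the kidney at 4 mg/kg, and a 4% NaCl diet for 7 days. The 3 rats labelled HS_DT received GapmeRs directed at Dnmt3a, a de novo DNA methyltransferase, and Tet3, an enzyme that oxidises methylated cytosine, at 2 mg/kg each, with the same diet. The depth of the libraries is unknown, and their relative depth was estimated at 0.761 to 1.37. Mitochondrially encoded transcripts made up 20.6% of the summed FPKM in HS_SCR replicate 3 and up to 31.9% in the other libraries. HS_SCR replicate 3 also stood apart on the second principal component (22.1% of the variance), at -51.5 against -2.34 to 24.0 in the other 8 libraries. Spearman correlations within HS_SCR were 0.931 to 0.968, against 0.979 to 0.983 within 0.4% salt and 0.968 to 0.984 within HS_DT. The rat numbers form a lower and a higher series, which the labels do not explain. All 3 rats of 0.4% salt and 1 rat of each high-salt group are in the higher series, so the series partly goes with the diet. In the high-salt groups these are HS_SCR replicate 3 and HS_DT replicate 3. A fit without either leaves its group with rats of the lower series only. The change of that group from 0.4% salt then goes wholly with the series.

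The transcripts of both targeted genes had their lowest group mean in the libraries labelled HS_SCR, not in those labelled HS_DT. Dnmt3a (rn5 chromosome 6, 38011928 to 38155093) averaged 12.8 ± 0.624 FPKM (SD, n = 3) in 0.4% salt, 7.70 ± 2.33 in HS_SCR and 9.999 ± 1.17 in HS_DT. Tet3 (chromosome 4, 179650809 to 179747550) averaged 9.16 ± 0.612, 6.24 ± 1.71 and 8.03 ± 0.465 FPKM. Between HS_DT and HS_SCR the log2 change of Dnmt3a was 0.37 ± 0.18 (SE; 95% interval -0.04 to 0.77), which did not pass (limma adjusted p = 0.303, exact permutation p = 0.3). That of Tet3 was 0.34 ± 0.15 (-0.01 to 0.69), which did not pass either (limma adjusted p = 0.271, exact permutation p = 0.3). Against 0.4% salt, Dnmt3a fell in HS_SCR by a log2 change of -0.70 ± 0.18 (limma adjusted p = 0.0367, exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Tet3 did not pass there (-0.51 ± 0.15, limma adjusted p = 0.0599, exact permutation p = 0.1). From 0.4% salt to HS_DT, Dnmt3a stood at -0.33 ± 0.18 (limma adjusted p = 0.730, exact permutation p = 0.1) and Tet3 at -0.17 ± 0.15 (limma adjusted p = 0.832, exact permutation p = 0.2).

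The fall of Dnmt3a in HS_SCR passed with all 9 libraries and without HS_SCR replicate 3 (limma adjusted p = 0.00231). It did not pass without any other library, with adjusted p from 0.0503 without HS_DT replicate 3 to 0.116 without 0.4% salt replicate 1. With the rat number series as a factor the change of Dnmt3a was -0.43 and did not pass (limma adjusted p = 0.112). Nor did it pass with no filter on low values (0.0573), with the proximal tubule score as a covariate (0.274), without the 2 libraries richest in proximal tubule markers (0.141) or in the fit of the 2 groups alone (0.0892). Without HS_SCR replicate 3, both genes were called higher in HS_DT than in HS_SCR, Dnmt3a at 0.57 (limma adjusted p = 0.0212) and Tet3 at 0.53 (limma adjusted p = 0.0143). In that fit Tet3 also fell in HS_SCR against 0.4% salt (-0.70, limma adjusted p = 0.00219). Without HS_SCR replicate 3, all HS_SCR rats are of the lower number series and all 0.4% salt rats of the higher. Group and series cannot be told apart in that comparison. With the rat number series as a factor, Tet3 stood at -0.33 in HS_SCR against 0.4% salt (limma adjusted p = 0.217). From 0.4% salt to HS_DT, the FPKM ranges of Dnmt3a did not overlap, and its change was called with library weights alone (-0.32, limma adjusted p = 0.0389). The targeted transcripts were not lower in the libraries labelled HS_DT than in those labelled HS_SCR, so the groups are named here by their labels. Relative to HS_SCR, the values do not show a reduction of Dnmt3a or Tet3 by the GapmeRs at the time of collection.

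**Figure D1:**
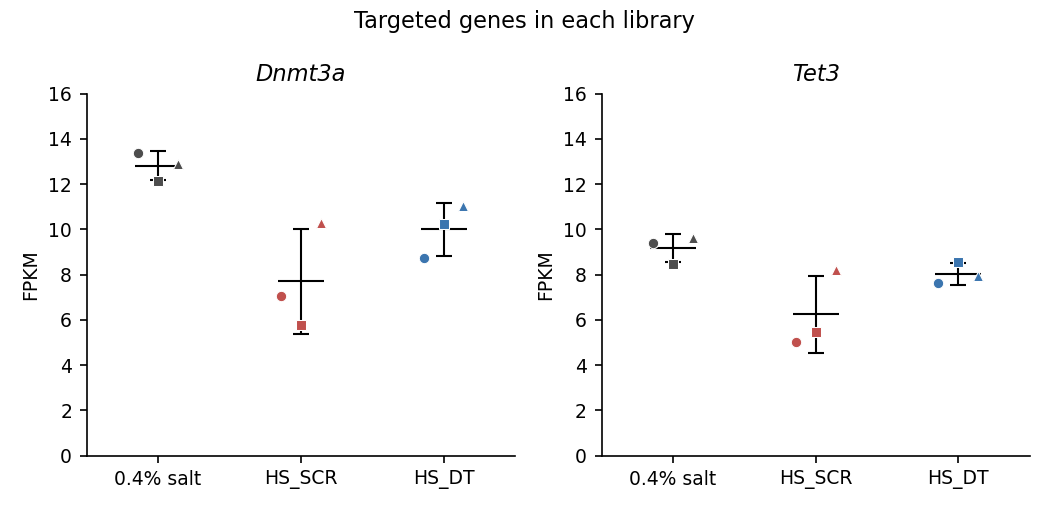
FPKM of Dnmt3a and Tet3 in each library, by group; symbols are the 3 libraries of a group and bars the mean with the SD. The libraries labelled HS_DT lie at 8.72 to 11.02 FPKM for Dnmt3a and those labelled HS_SCR at 5.75 to 10.3.

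Against 0.4% salt, the libraries labelled HS_SCR held less RNA of proximal tubule and thick ascending limb markers and more RNA of ribosomal proteins, tubular injury genes, macrophage genes and haemoglobins. The comparison asks what differs after the high-salt diet in this strain. It takes in the scrambled GapmeR and the 7 days as well, since no group received either alone. Of 14338 loci, 1175 rose and 699 fell, 309 of them by more than 2-fold. S100a9 and S100a8, calcium-binding proteins of neutrophils, rose most. S100a9 went from 2.47 ± 0.323 to 105.5 ± 104.9 FPKM (log2 change 4.50 ± 0.58, adjusted p = 0.00638) and S100a8 from 2.49 ± 0.855 to 91.2 ± 101.1 FPKM (4.15 ± 0.69). S100a9 reached 227 FPKM in HS_SCR replicate 2 and 46.7 and 43.2 in the other HS_SCR libraries. Alox15, a lipoxygenase (2.25 ± 0.41), Serpina3n, a protease inhibitor of the acute phase (2.22 ± 0.29), and Cfd, complement factor D (2.22 ± 0.32), rose as well. Igfbp1, which binds insulin-like growth factors, rose from 57.7 ± 8.12 to 286 ± 122 FPKM (adjusted p = 0.00723). FPKM ranges did not overlap at 4805 loci, 33.5% against 10% expected per locus by chance, and 4591 loci had an unadjusted p under 0.05. Since loci vary together, the share over all loci can lie far from 10% by chance. That share was not measured in exchanged groups.

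The proximal tubule markers were lower as a group in HS_SCR. All 20 measured members had a lower mean than in 0.4% salt, with a median log2 change of -2.71. Of these, 5 fell over all genes tested, and 14 fell when adjusted over the list alone. The list passed by camera (adjusted p = 4.9e-07; adjusted p = 0.521 with an estimated correlation). It did not pass with its own score as a covariate (median 0.05, adjusted p = 0.961). That score is made from the same genes, so the fit removes their mean change by construction. Miox, which breaks down inositol, fell from 168 ± 112 to 8.67 ± 9.82 FPKM (log2 change -4.43 ± 0.90, adjusted p = 0.0186). Slc34a1, the phosphate cotransporter of the brush border, fell from 133 ± 86.1 to 12.3 ± 15.6 FPKM (-3.85 ± 0.97, adjusted p = 0.0365). Gatm, an enzyme of creatine synthesis, fell from 209 ± 114 to 27.1 ± 29.2 FPKM (-3.28 ± 0.80). Slc22a6, an organic anion transporter, fell from 26.9 ± 15.2 to 1.97 ± 2.52 FPKM (-3.41 ± 0.86). The other large falls were Slco1a6 (-3.40), Mep1a, a brush-border protease (-3.35), Tmem27 (-3.26), Ces1d (-3.16), Hnmt (-2.92) and Hao2 (-2.80). The proximal tubule score of the libraries varied within each group, at 5.01, 6.46 and 5.38 in 0.4% salt, 2.199, 4.29 and 2.93 in HS_SCR and 3.78, 4.16 and 6.02 in HS_DT.

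Markers of the thick ascending limb were also lower as a group. Of the 14 markers of this segment, 4 fell, 1 rose and 9 did not pass, with a median log2 change of -0.67 (5 fell and 1 rose when adjusted over the list alone). Camera called the list (adjusted p = 0.00161; adjusted p = 0.521 with an estimated correlation), and without HS_SCR replicate 3 the median was -0.35 (adjusted p = 0.0475). SLC12A1, the Na-K-2Cl cotransporter blocked by loop diuretics (chromosome 3, 123944406 to 124022076), fell from 880.0 ± 124 to 469 ± 15.9 FPKM (-0.90 ± 0.11, adjusted p = 0.00638). A second SLC12A1 entry at the same position fell from 18.8 ± 3.43 to 4.93 ± 1.32 FPKM. Egf fell from 28.8 ± 6.53 to 5.91 ± 4.09 FPKM (-2.36 ± 0.50, adjusted p = 0.0217), Casr, the calcium-sensing receptor, by -1.60 ± 0.25 and Tmem72 by -1.13 ± 0.16. The wider list of sodium transport genes and their regulators held 4 falls and 1 rise among 26, over all genes and adjusted over the list alone, with a median of -0.09. It passed narrowly by camera (adjusted p = 0.0399; adjusted p = 0.521 with an estimated correlation). Its falls included Slc9a3, the apical sodium-proton exchanger (39.8 ± 7.02 to 10.1 ± 5.81 FPKM, -2.04 ± 0.39), and Kcnj10, a basolateral potassium channel (-1.67 ± 0.31). That call ended without 0.4% salt replicate 1 (median -0.06, adjusted p = 0.0681), 0.4% salt replicate 2 (median -0.05, 0.0809), HS_SCR replicate 1 (median -0.11, 0.0726) or HS_SCR replicate 3 (median -0.13, 0.0593). It also ended with no filter on low values (median -0.09, 0.0622), with the proximal tubule score as a covariate (median -0.05, 0.128) and without the 2 libraries richest in proximal tubule markers (median -0.05, 0.0939). With the locus-width trend removed the median of sodium transport genes turned to 0.02 (adjusted p = 0.159).

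Markers of the collecting duct principal cell, which takes up sodium through its apical channel, had 11 of 11 means higher, with a median of 0.43 and no member called by limma. Hsd11b2 stood at 0.43 ± 0.16 and Krt19 at 0.83 ± 0.29. Principal cell markers passed by camera (adjusted p = 0.0286; adjusted p = 0.682 with an estimated correlation), and that call ended without 0.4% salt replicate 3 (median 0.26, adjusted p = 0.168), HS_SCR replicate 1 (median 0.31, 0.0943) or HS_SCR replicate 3 (median 0.33, 0.139). It also ended at a minimum mean of 5 FPKM (median 0.43, 0.0658), under quantile normalization (median 0.29, 0.0923), with library weights (median 0.19, 0.216), with the rat number series as a factor (median 0.37, 0.0752), with the locus-width trend removed (median 0.43, 0.0746) and with the proximal tubule score as a covariate (median 0.08, 0.961). Intercalated cell, thin limb, podocyte, endothelial, pericyte and lymphocyte markers gave medians from -0.18 to 0.21 and no call. Intercalated cell markers passed under quantile normalization (median -0.22, adjusted p = 0.0337) and thin limb markers with the rat number series as a factor (median -0.39, 0.0445). Podocyte markers had a median of -0.07 and a mean of 0.04, with camera direction lower, and lymphocyte markers a median of -0.01 and a mean of 0.11, with camera direction higher. Among these, Pecam1 (0.39 ± 0.10) and EGFL7 (0.80 ± 0.12) of the endothelium, Wt1 (0.95 ± 0.21) of the podocyte, Mcam (0.47 ± 0.10) of the pericyte list and Cd79b (0.91 ± 0.24) of lymphocytes rose, Cd79b not when adjusted over its list alone. Podxl of the podocyte (-0.68 ± 0.13), Notch3 of the pericyte list (-0.46 ± 0.10) and Aqp1 of the thin limb (-0.69 ± 0.19) fell.

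Injury, macrophage and blood cell genes were higher in HS_SCR, and inflammatory cytokine, chemokine and adhesion genes did not pass as a list with all 9 libraries. Of 20 inflammatory genes, Selp rose (1.10 ± 0.18) and 19 did not pass, with a median of 0.26 (camera adjusted p = 0.228). Without HS_SCR replicate 3 that list passed (median 0.32, adjusted p = 0.0475), in a fit whose HS_SCR rats are all of the lower number series. Of 17 tubular injury genes, 8 rose and 9 did not pass, with a median of 0.80 (11 rose when adjusted over the list alone). The injury list passed by camera (adjusted p = 3.6e-06; adjusted p = 0.521 with an estimated correlation). Lcn2, a marker of tubular damage, rose from 146 ± 36.9 to 616 ± 251 FPKM (2.00 ± 0.31, adjusted p = 0.00835). The keratins Krt8 (1.01 ± 0.14) and Krt18 (1.18 ± 0.20) and the cell cycle inhibitor Cdkn1a (0.99 ± 0.23) rose with it. Of 17 macrophage and myeloid markers, 9 rose and 8 did not pass, with a median of 0.85 (13 rose when adjusted over the list alone). Macrophage markers passed by camera (adjusted p = 3.1e-07; adjusted p = 0.521 with an estimated correlation). The complement genes C1qa (1.28 ± 0.16), C1qb (1.63 ± 0.15) and C1qc (126 ± 18.3 to 362 ± 25.8 FPKM, 1.52 ± 0.11, adjusted p = 0.00219) and the mannose receptor Mrc1 (1.48 ± 0.31) were among them.

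All 5 measured erythroid markers rose, with a median of 2.41, over all genes and when adjusted over the list alone. The erythroid list passed by camera (adjusted p = 0.000743; adjusted p = 0.521 with an estimated correlation). Hba1 rose from 631 ± 146 to 4946 ± 3505 FPKM (2.62 ± 0.59, adjusted p = 0.0261), Hbb-b1 by 2.41 ± 0.62, and the genes of red cell precursors Alas2 by 2.61 ± 0.52 and Ahsp by 2.26 ± 0.41. Hba1 stood at 8246 and 5325 FPKM in HS_SCR replicates 1 and 2 and at 1267 in HS_SCR replicate 3. Of 23 genes of extracellular matrix and fibrosis, 6 rose and 17 did not pass, with a median of 0.49 (8 rose when adjusted over the list alone). Vim rose by 0.96 ± 0.14, Timp1 by 0.98 ± 0.22, Lox by 1.14 ± 0.28 and Col6a1 by 0.65 ± 0.16. The matrix list passed by camera (adjusted p = 0.00125; adjusted p = 0.521 with an estimated correlation). That call ended without HS_SCR replicate 3 (median 0.27, adjusted p = 0.0593), under quantile normalization (median 0.29, 0.0946) and with the proximal tubule score as a covariate (median 0.16, 0.184), with the same direction.

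Ribosomal protein genes rose together. Of the 40 measured, 38 rose, over all genes tested and when adjusted over the list alone, all 40 means were higher, and the median log2 change was 0.65. The ribosomal list passed by camera (adjusted p = 1.4e-25; adjusted p = 0.521 with an estimated correlation) and by fry (adjusted p = 0.000544). Rpl32 rose from 1099 ± 79.5 to 1871 ± 127 FPKM (0.77 ± 0.10, adjusted p = 0.00629). Rplp1 rose by 0.76 ± 0.10 and Rps27 by 0.81 ± 0.12.

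Genes of mitochondrial energy metabolism were lower in HS_SCR. Of 61 genes of oxidative phosphorylation and the citrate cycle, 6 fell and 55 did not pass, with a median of -0.17 (5 fell when adjusted over the list alone). Ogdh (-0.52), Dlst (-0.61) and Ndufs1 (-0.65) fell. The oxidative phosphorylation list passed by camera (adjusted p = 0.000573; adjusted p = 0.753 with an estimated correlation), and that call ended without HS_SCR replicate 3 (median 0.01, adjusted p = 0.664) and with library weights (median -0.08, 0.0631). Of 29 genes of fatty acid oxidation, 4 fell, 1 rose and 24 did not pass, with a median of -0.19 (6 fell and 2 rose when adjusted over the list alone). The fatty acid list passed by camera (adjusted p = 0.00279; adjusted p = 0.521 with an estimated correlation), and that call ended with the proximal tubule score as a covariate (median -0.06, adjusted p = 0.638). The regulators Ppara (-0.78 ± 0.14) and Ppargc1a (49.9 ± 5.62 to 20.5 ± 9.51 FPKM, -1.33 ± 0.29) fell and Angptl4, an inhibitor of lipoprotein lipase, rose (0.95 ± 0.26). Of 24 genes of NADPH oxidase and oxidative stress, Gpx1 (0.77 ± 0.13), Txn1 (0.46 ± 0.08) and Cybb (0.36 ± 0.10) rose and Gclc, of glutathione synthesis, fell (-2.69 ± 0.53). The same 3 rises and 1 fall were called when adjusted over the list alone, and the median was 0.28. The oxidative stress list passed by camera (adjusted p = 0.0390; adjusted p = 0.521 with an estimated correlation). That call ended without 0.4% salt replicate 1 (median 0.32, adjusted p = 0.0644), 0.4% salt replicate 3 (median 0.25, 0.102), HS_SCR replicate 2 (median 0.26, 0.0606) or HS_SCR replicate 3 (median 0.26, 0.0593). It also ended under quantile normalization (median 0.18, 0.329), at a minimum mean of 5 FPKM (median 0.29, 0.163) and with the locus-width trend removed (median 0.25, 0.0746).

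The genes that write, erase and read DNA methylation did not shift as a group. Of 15 measured, 2 rose, 1 fell and 12 did not pass (2 rose and 4 fell when adjusted over the list alone). Mbd2, which binds methylated DNA, rose (0.33 ± 0.09, adjusted p = 0.0463), Gadd45b rose (12.5 ± 1.95 to 26.8 ± 5.78 FPKM, 1.02 ± 0.18, adjusted p = 0.0123) and Dnmt3a fell. The camera adjusted p was 0.740 with direction lower, at a median of 0.11 and a mean of -0.06. No member of the 13 measured imprinted genes was called by limma (median -0.15, camera adjusted p = 0.458), with Igf2r at -0.45 ± 0.17 and PHLDA2 at -0.81 ± 0.35. Of 20 genes of the renin-angiotensin and other vasoactive systems, 3 rose and 2 fell (3 rose and 5 fell when adjusted over the list alone). Their camera adjusted p was 0.590 with direction lower, at a median of 0.06 and a mean of -0.16, and they passed with the proximal tubule score as a covariate (median -0.13, adjusted p = 0.0477). Edn1, the endothelin made in the collecting duct, rose (0.64 ± 0.18), as did Ptger4, a prostaglandin receptor (0.51 ± 0.10). Edn3 (-1.81 ± 0.49) and Nr3c1, the glucocorticoid receptor (-0.47 ± 0.08), fell.

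Of the 31 lists, 17 passed by camera, 9 higher and 8 lower. None passed with an estimated correlation (2 had an unadjusted p under 0.05), and fry called 7. The number of genes called depended on single libraries. It was 448, 347 and 958 without 0.4% salt replicates 1, 2 and 3, 909 without HS_SCR replicate 2, 5188 without HS_SCR replicate 3 and 1075 without HS_DT replicate 2. The count without HS_SCR replicate 3 compares groups that also differ wholly in the rat number series. Of the 87 named genes called here, 25 passed in all 9 such fits, among them C1qc, SLC12A1, Lcn2 and Rpl32. With the proximal tubule score as a covariate limma called 0 genes (2154 at an unadjusted p under 0.05), and without 0.4% salt replicate 2 and HS_DT replicate 3 it called 0 (3010). The score itself differed between the groups, at 5.01 to 6.46 in 0.4% salt and 2.199 to 4.29 in HS_SCR. The covariate fit therefore loses precision: the SE of Dnmt3a went from 0.18 to 0.29, with changes of -0.70 and -0.77. Its loss of calls does not show that proximal tubule content accounts for the changes. The fit of these 2 groups alone called 466, and library weights 4019.

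**Figure D2:**
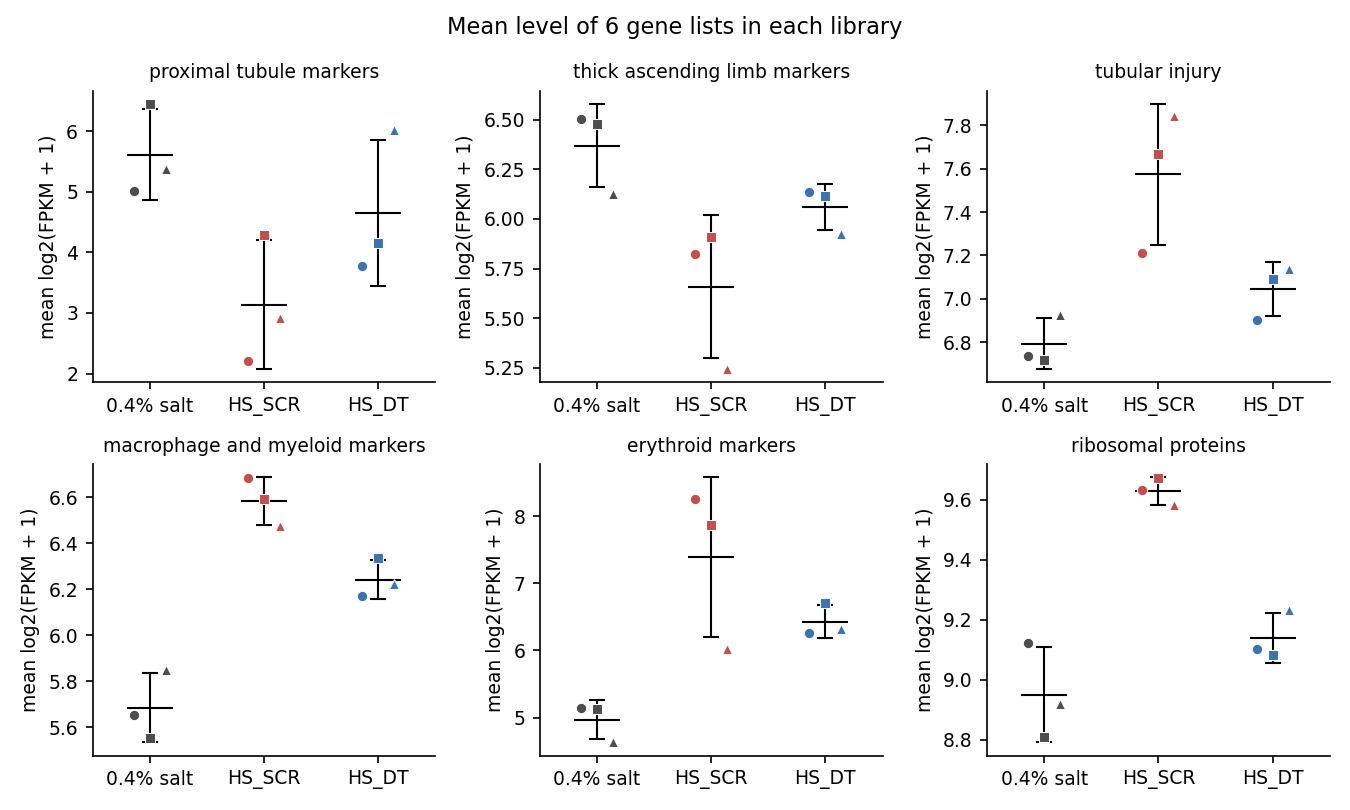
Mean log2(FPKM + 1) of the members of 6 gene lists in each library, by group; symbols are libraries and bars the mean with the SD. For ribosomal proteins the libraries labelled HS_SCR lie at 9.58 to 9.67 and all others at 8.81 to 9.23.

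**Figure D3:**
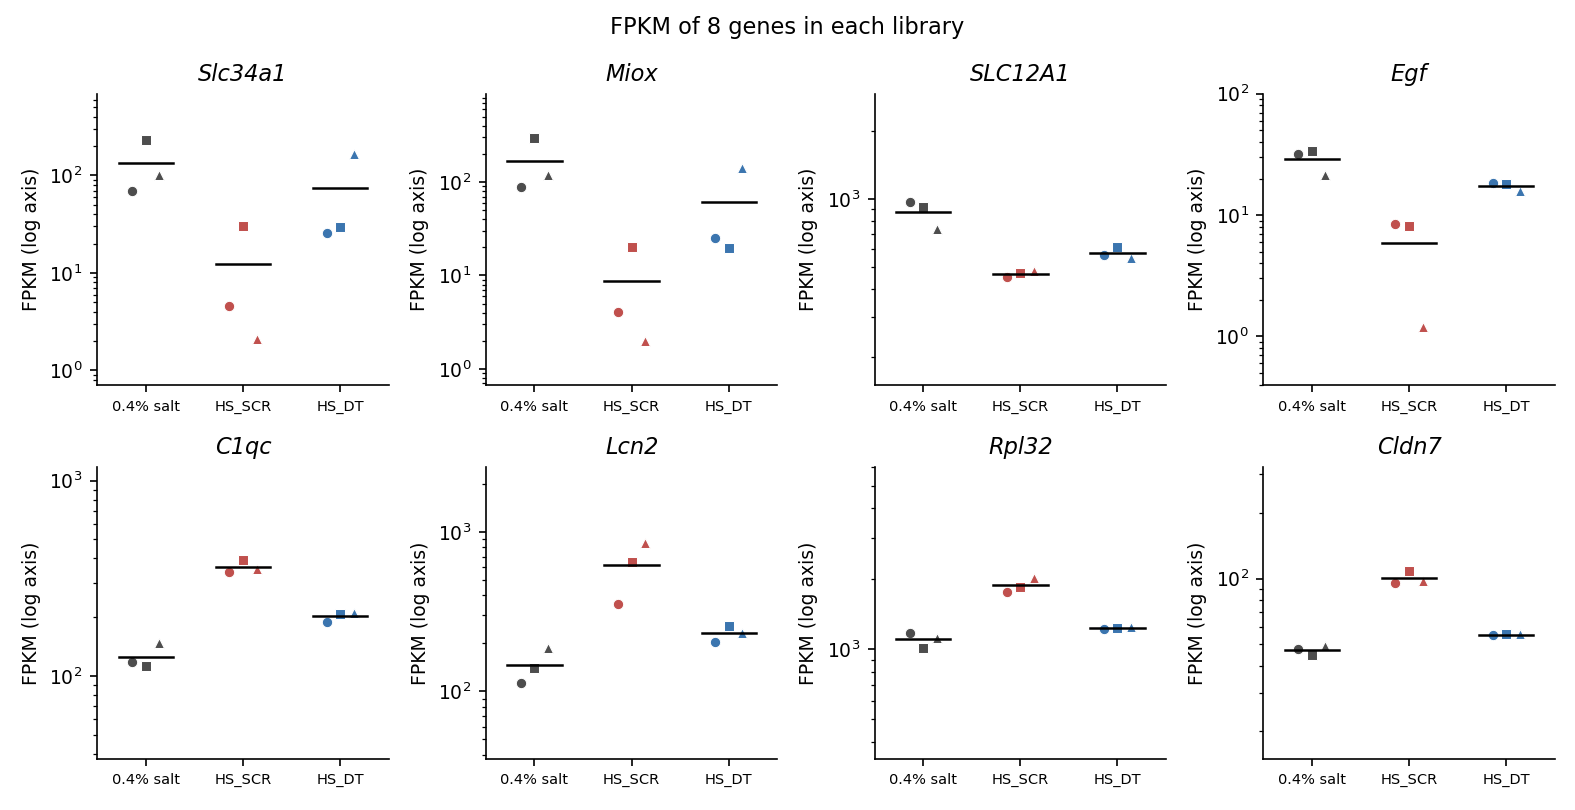
FPKM of 8 genes in each library on a logarithmic axis; symbols are libraries and lines the group means. In the libraries labelled HS_DT, C1qc (190.0 to 209 FPKM) lies between 0.4% salt (113 to 147) and HS_SCR (342 to 391).

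Compared with HS_SCR, the libraries labelled HS_DT held less Cldn7. As lists called by camera with the preset correlation, ribosomal protein, tubular injury and macrophage genes were lower. Proximal tubule, cholesterol synthesis and cell cycle genes were higher as lists. None of these calls held with an estimated correlation. Exchanging libraries between the groups gave as many called lists in 4 of 10 splits, the real one included. This comparison asks what the GapmeRs against Dnmt3a and Tet3 change on the high-salt diet, although neither targeted transcript was lower in HS_DT than in HS_SCR. Cldn7, a claudin of the tight junctions of distal tubules and collecting ducts (chromosome 10, 56321560 to 56323745), was the single gene called. Cldn7 fell from 100.2 ± 6.98 to 55.5 ± 0.455 FPKM (log2 change -0.84 ± 0.07, adjusted p = 0.0307). From 0.4% salt to HS_SCR it had risen from 47.2 ± 2.07 FPKM (1.07 ± 0.07, adjusted p = 0.00212).

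Of the 40 ribosomal protein genes, 39 fell when adjusted over the list alone and 0 over all genes tested by limma (2732 loci at an unadjusted p under 0.05). All 40 means were lower, with a median of -0.47. Ribosomal proteins passed by camera (adjusted p = 5.7e-29; adjusted p = 0.694 with an estimated correlation) and by fry (adjusted p = 0.00357). Rpl13 stood at 971 ± 32.4 FPKM in HS_SCR and 666 ± 20.2 in HS_DT (-0.54 ± 0.09, adjusted p = 0.0644). Tubular injury genes had 16 of 17 means lower and 7 falls when adjusted over the list alone, with a median of -0.55. Injury genes passed by camera (adjusted p = 7.0e-06; adjusted p = 0.791 with an estimated correlation). Krt8 stood at 152 ± 25.9 and 84.6 ± 12.9 FPKM and Anxa1 at 509.8 ± 48.9 and 343 ± 30.8 FPKM.

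Macrophage markers had a median of -0.22, with 4 falls when adjusted over the list alone. They passed by camera (adjusted p = 0.0279; adjusted p = 0.813 with an estimated correlation). C1qb stood at -0.93 ± 0.15 and C1qc at 362 ± 25.8 and 203 ± 10.9 FPKM (-0.83 ± 0.11, adjusted p = 0.0644). The macrophage call ended without HS_SCR replicate 1 (median -0.09, adjusted p = 0.370), HS_DT replicate 1 (median -0.19, 0.0705) or HS_DT replicate 3 (median -0.18, 0.0549). It also ended under quantile normalization (median -0.02, 0.388), at a minimum mean of 5 FPKM (median -0.22, 0.0869), with library weights (median -0.26, 0.0629), with the locus-width trend removed (median -0.12, 0.0514) and with the proximal tubule score as a covariate (median -0.09, 0.204). Erythroid markers had a median of -0.997, with 1 fall when adjusted over the list alone, Ahsp at -1.43 ± 0.41 and Alas2 at -1.07 ± 0.52. Erythroid genes passed by camera (adjusted p = 0.0399; adjusted p = 0.813 with an estimated correlation). The erythroid call ended without HS_SCR replicate 1 (median -0.44, adjusted p = 0.281), HS_SCR replicate 2 (median -0.76, 0.133), HS_DT replicate 1 (median -0.94, 0.0990) or HS_DT replicate 3 (median -0.91, 0.0695). It also ended under quantile normalization (median -0.49, 0.0888), with the proximal tubule score as a covariate (median -0.93, 0.0964), with the locus-width trend removed (median -0.88, 0.0517) and without the 2 libraries richest in proximal tubule markers (median -0.91, 0.0788).

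Among the groups that were higher in HS_DT, cholesterol synthesis had 11 rises and 1 fall of 23 when adjusted over the list alone, with a median of 0.49. Cholesterol genes passed by camera (adjusted p = 9.9e-07; adjusted p = 0.813 with an estimated correlation). Stard4, which carries cholesterol between membranes, stood at 0.67 ± 0.11. All 24 cell cycle genes had a higher mean, with a median of 0.42 and 0 called by limma, over all genes tested (2732 loci at an unadjusted p under 0.05) or adjusted over the list alone. Cell cycle genes passed by camera (adjusted p = 4.8e-06; adjusted p = 0.813 with an estimated correlation), with Mcm2 at 0.50 ± 0.15 and Tyms at 0.42 ± 0.12. Without HS_SCR replicate 3 the cell cycle median was 0.19 (adjusted p = 0.0497). The mean log2 value of these genes was 3.30, 2.88 and 2.42 in HS_SCR and 3.12, 3.26 and 3.43 in HS_DT. HS_SCR replicate 1 thus lay above HS_DT replicates 1 and 2. Interferon-stimulated genes had 22 of 24 means higher, with a median of 0.41 and Ifit2 at 0.55 ± 0.14. Interferon genes passed by camera (adjusted p = 2.6e-05; adjusted p = 0.813 with an estimated correlation), and that call ended without HS_SCR replicate 3 (median 0.18, adjusted p = 0.111). The interferon median was 0.71 without HS_SCR replicate 1, and without HS_SCR replicate 3 the medians of macrophage and erythroid markers were -0.36 and -1.77.

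Proximal tubule markers had 18 of 20 means higher in HS_DT, with a median of 1.37, Miox at 2.64 ± 0.90 and Slc22a12, the urate transporter, at 1.98 ± 0.70. They passed by camera (adjusted p = 6.0e-05; adjusted p = 0.813 with an estimated correlation), and HS_DT replicate 3 had the highest proximal tubule score of the group. The scores were 3.78, 4.16 and 6.02 in HS_DT and 2.199, 4.29 and 2.93 in HS_SCR. HS_SCR replicate 2 thus lay above HS_DT replicates 1 and 2, and much of the rise came from HS_DT replicate 3. Without HS_DT replicate 3 the median was 0.49 (adjusted p = 0.0293). That call ended with library weights (median 0.89, adjusted p = 0.0621). It also ended with the score as a covariate (median -0.28, 0.823), a fit that removes the mean change of these genes by construction. Thick ascending limb markers had a median of 0.36 (3 rises and 1 fall when adjusted over the list alone), with Tmem72 at 0.63 ± 0.16 and Casr at 0.92 ± 0.25. The thick limb list passed by camera (adjusted p = 0.0386; adjusted p = 0.813 with an estimated correlation). That call ended without HS_SCR replicate 3 (median 0.07, adjusted p = 0.440), HS_DT replicate 1 (median 0.30, 0.0990) or HS_DT replicate 2 (median 0.31, 0.0689). It also ended with library weights (median 0.24, 0.194), with the proximal tubule score as a covariate (median 0.44, 0.0530) and with the locus-width trend removed (median 0.32, 0.0514). Oxidative phosphorylation (median 0.08) and fatty acid oxidation (0.13) passed by camera with an adjusted p of 0.0279 each (adjusted p = 0.813 with an estimated correlation). Dlst stood at 0.36 ± 0.11, Uqcrc2 at 0.28 ± 0.09, Ppara at 0.44 ± 0.14 and Ppargc1a at 0.88 ± 0.29. The first call ended without HS_SCR replicate 3 (median -0.11, adjusted p = 0.271) or HS_DT replicate 1 (median 0.01, 0.375) and with library weights (median -0.08, 0.552). The second ended without HS_SCR replicate 1 (median 0.13, 0.122), HS_SCR replicate 3 (median 0.10, 0.0725) or HS_DT replicate 3 (median 0.09, 0.101), with library weights (median 0.11, 0.208), with the proximal tubule score as a covariate (median 0.04, 0.803) and without the 2 libraries richest in proximal tubule markers (median 0.09, 0.0889).

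Beyond Cldn7, the genes with the smallest unadjusted p had an adjusted p of 0.0644 and did not pass. Higher in HS_DT were Plekha6 (0.57), Rbl1 (0.83), Brcc3 (0.49), ASPH (0.65), Immp2l (1.82), Caln1 (1.22), Ephb2 (0.67), Scrn3 (0.48), Tmem116 (0.87) and Lmod1 (1.09). Lower were C1qc, the renal transcription factor Pax8 (94.4 ± 8.34 and 55.9 ± 5.33 FPKM, -0.75), Blnk (-0.57), Maf1 (-0.46), Vasn (-0.52), Rps4x (-0.60), Cnppd1 (-0.64), Rps28 (-0.67) and Cd99 (-0.64). In the methylation list Uhrf1 stood at 0.81 ± 0.22 and Gadd45b at -0.64 ± 0.18. That list did not pass (median 0.03, camera adjusted p = 0.959 with direction lower), nor did imprinted genes (median 0.13, camera adjusted p = 0.647).

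At an unadjusted p under 0.05 there were 2732 loci, and FPKM ranges did not overlap at 3103 loci (21.6%). The 10% expected per locus by chance does not bound this share, since loci vary together. Camera called 11 of the 31 lists, 7 higher and 4 lower, none with an estimated correlation (1 at an unadjusted p under 0.05), and fry called 1. The gene count was 154 at a minimum mean of 5 FPKM, 422 with the rat number series as a factor, 180 without HS_SCR replicate 1, 2300 without HS_SCR replicate 3 and 1496 with library weights. Cldn7 lost its call under quantile normalization (adjusted p = 0.103), with the replicate block (0.0821), with the locus-width trend removed (0.0522), without the 2 libraries richest in proximal tubule markers (0.316), with the proximal tubule score as a covariate (0.151) and in the fit of the 2 groups alone (0.193). It also lost it without any single library other than HS_SCR replicate 1 (0.0121) or HS_SCR replicate 3 (0.0125). Its log2 change stayed between -0.73 (quantile normalization) and -0.87 (without HS_SCR replicate 1) in all fits.

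**Figure D4:**
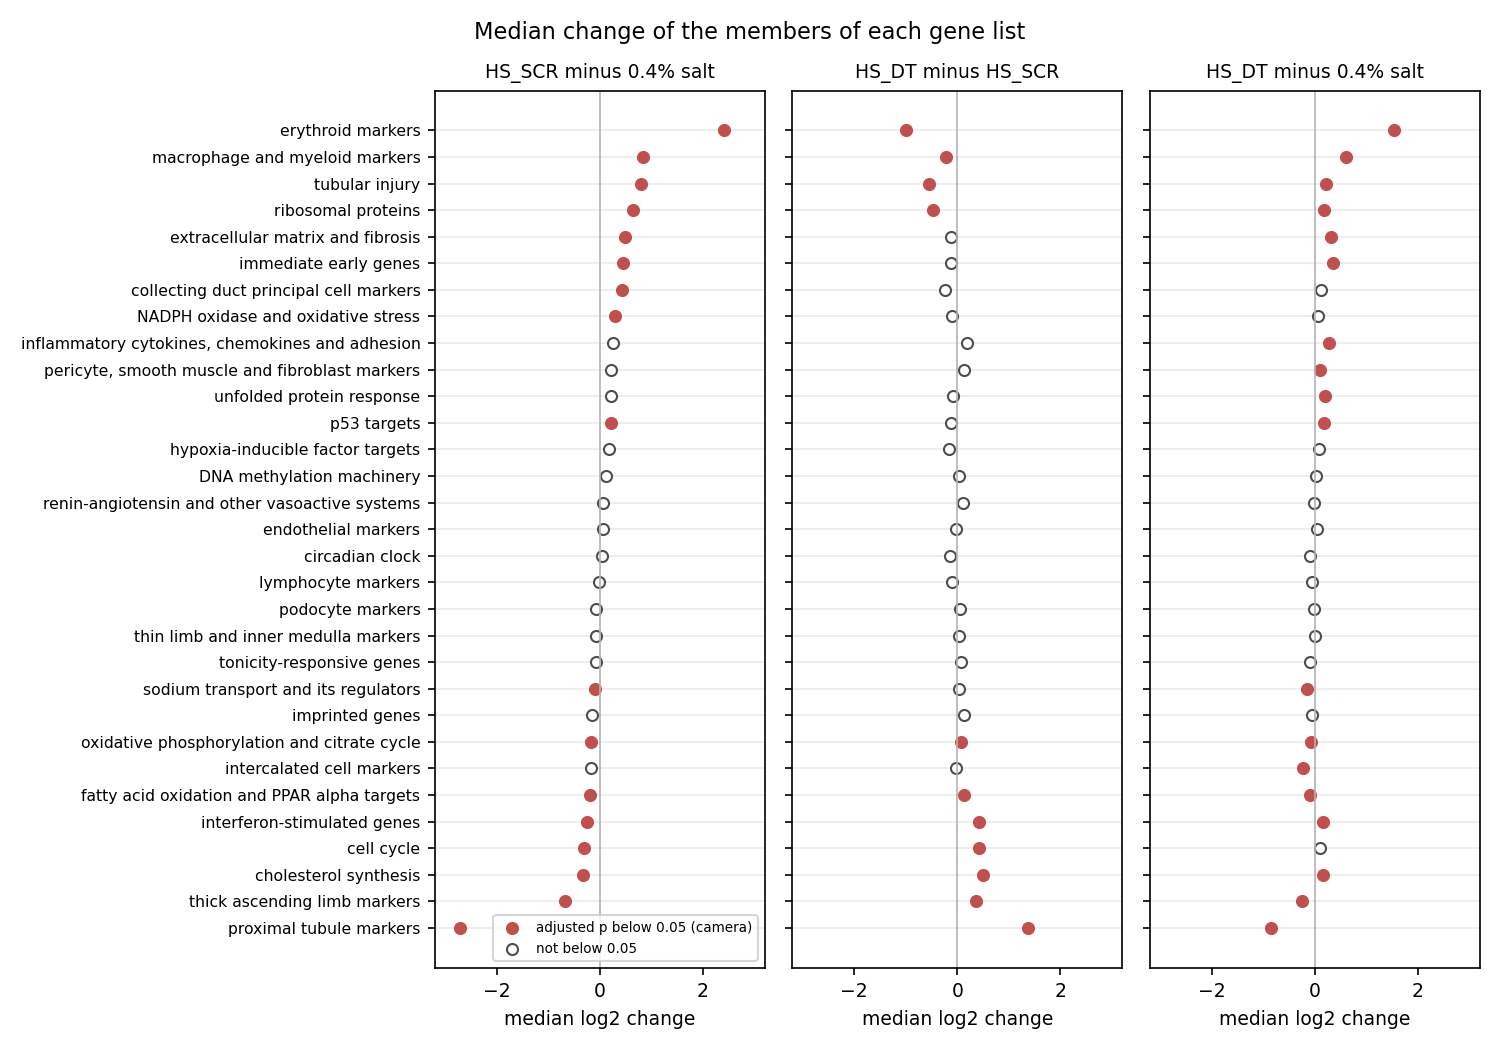
Median log2 change of the tested members of 31 gene lists in the 3 comparisons; filled points have a camera adjusted p under 0.05 with the preset correlation, and open points do not. Proximal tubule markers lie at -2.71, 1.37 and -0.85 and ribosomal proteins at 0.65, -0.47 and 0.18.

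Compared with 0.4% salt, the libraries labelled HS_DT held more RNA of macrophage, erythroid and matrix genes and less of proximal tubule and thick ascending limb markers. The medians were smaller in size than in HS_SCR. Inflammatory genes passed as a list, with higher mean values in HS_DT replicates 1 and 2 and not in HS_DT replicate 3. The comparison joins diet, GapmeRs and the 7 days. Limma called 0 of 14338 loci (1074 at an unadjusted p under 0.05; smallest adjusted p 0.0643). Macrophage markers had 17 of 17 means higher, with a median of 0.61 and 13 rises when adjusted over the list alone. Myeloid genes passed by camera (adjusted p = 7.4e-13; adjusted p = 0.371 with an estimated correlation). Cd68 stood at 41.5 ± 4.41 FPKM in 0.4% salt and 66.3 ± 6.40 in HS_DT (0.67 ± 0.12), and C1qc at 0.69 ± 0.11. Erythroid markers had a median of 1.54 with 4 rises when adjusted over the list alone, Hbb-b1 at 1.84 ± 0.62 and Hba2 at 1.46 ± 0.41. They passed by camera (adjusted p = 8.4e-05; adjusted p = 0.430 with an estimated correlation).

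Extracellular matrix genes (median 0.31, camera adjusted p = 8.4e-05), tubular injury genes (0.22, 0.00234), inflammatory genes (0.28, 0.000540) and ribosomal proteins (0.18, 1.3e-11) were higher by camera. Each of these 4 lists had an adjusted p = 0.430 with an estimated correlation. Vim stood at 0.55 ± 0.14, Col6a1 at 0.46 ± 0.16, Cdkn1a at 0.74 ± 0.23 and Anxa2 at 0.36 ± 0.11. Il1b, a cytokine of macrophages, stood at 1.51 ± 0.47, Selp, an adhesion protein, at 0.65 ± 0.18, Rpl10 at 0.24 ± 0.08 and Rpsa at 0.25 ± 0.08. The ribosomal call ended under quantile normalization (median 0.05, 0.0688), and the injury call without the 2 libraries richest in proximal tubule markers (median 0.12, 0.116). With the rat number series as a factor the median of inflammatory genes turned to -0.12 and the call ended (adjusted p = 0.820). Without HS_DT replicate 3 the inflammatory median was 0.43 (camera adjusted p = 2.8e-06), in a fit whose HS_DT rats are all of the lower number series. The mean log2 value of these genes was 4.56, 4.65 and 4.09 in HS_DT replicates 1, 2 and 3. It was 4.00 to 4.13 in 0.4% salt.

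Proximal tubule, thick ascending limb and intercalated cell markers and sodium transport genes were lower as lists in HS_DT than in 0.4% salt. Proximal tubule markers had 20 of 20 means lower, with a median of -0.85, Miox at -1.78 ± 0.90 and Slc13a3 at -1.44 ± 0.86. Proximal markers passed by camera (adjusted p = 9.3e-05; adjusted p = 0.524 with an estimated correlation). That call ended with the rat number series as a factor (median -0.24, adjusted p = 0.516). It also ended with their score as a covariate (median 0.03, 0.723), which removes their mean change by construction. Thick ascending limb markers (median -0.25, camera adjusted p = 0.000724) and sodium transport genes (-0.16, camera adjusted p = 0.00268) passed (adjusted p = 0.430 with an estimated correlation for both). SLC12A1 stood at 880.0 ± 124 FPKM in 0.4% salt and 576 ± 33.6 in HS_DT (-0.60 ± 0.11, adjusted p = 0.270), Tmem72 at -0.50 ± 0.16 and Stk39 at -0.27 ± 0.10. Without HS_DT replicate 3 the median of proximal tubule markers was -1.54, and without 0.4% salt replicate 1 that of thick limb markers was -0.13 (adjusted p = 0.00579). The thick limb call ended without the 2 libraries richest in proximal tubule markers (median -0.21, 0.0810). Markers of the intercalated cells, which secrete acid into the collecting duct, had 10 of 10 means lower, with a median of -0.23. Intercalated cell markers passed by camera (adjusted p = 3.5e-05; adjusted p = 0.130 with an estimated correlation), with Atp6v1b1 at 40.9 ± 2.196 and 31.2 ± 0.858 FPKM and Atp6v0d2 at -0.23 ± 0.07. Oxidative phosphorylation was lower (median -0.07, camera adjusted p = 0.000799; adjusted p = 0.780 with an estimated correlation), with Sdha at -0.27 ± 0.10 and Ogdh at -0.22 ± 0.10. Its median was -0.14 without HS_DT replicate 1 (camera adjusted p = 2.6e-06). Fatty acid oxidation was lower (median -0.09, camera adjusted p = 0.0181; adjusted p = 0.508 with an estimated correlation), with Plin2 at 0.48 ± 0.15 and Angptl4 at 0.65 ± 0.26. The first call ended without 0.4% salt replicate 1 (median -0.04, 0.0928) and without the 2 libraries richest in proximal tubule markers (median -0.03, 0.117). The second ended without 0.4% salt replicate 2 (median -0.03, 0.268), HS_DT replicate 1 (median -0.08, 0.0574) or HS_DT replicate 2 (median -0.06, 0.0582), with the rat number series as a factor (median -0.04, 0.308) and with the proximal tubule score as a covariate (median -0.06, 0.487).

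The genes with the smallest unadjusted p did not pass. B3galnt1 (13.99 ± 1.37 and 25.1 ± 0.319 FPKM, 0.80 ± 0.08) and the complement gene C3 (8.03 ± 0.326 and 26.2 ± 5.11 FPKM, 1.58 ± 0.17) were higher in HS_DT, each with an adjusted p of 0.0643. Higher too were Zyx (0.50), Lilrb4 (1.17), Siglec5 (0.94), Naaa (1.58), Bcat1 (0.79), Lst1 (1.41) and Chi3l1 (1.39). Lower were Pax2 (-0.68), Plekha6 (-0.38), Tmem207 (-1.07), BC030336 (-0.62), Hgf (-0.51), Ndrg3 (-0.52), Nefl (-1.24), Kcnip4 (-0.62) and Nefm (-1.04). The methylation list (median 0.03, mean -0.04, camera adjusted p = 0.577 with direction lower; Mbd4 -0.38 ± 0.15) and imprinted genes (-0.05, camera adjusted p = 0.444; Mest -0.79 ± 0.26) did not pass. FPKM ranges did not overlap at 3416 loci (23.8%). The 10% expected per locus by chance does not bound that share either, since loci vary together. Camera called 18 lists, 12 higher and 6 lower. None passed with an estimated correlation (2 at an unadjusted p under 0.05), and fry called 0 (7 at an unadjusted p under 0.05). With library weights limma called 1805 genes, at a minimum mean of 5 FPKM 2, in the fit of the 2 groups alone 1, without 0.4% salt replicate 3 1, and without HS_SCR replicate 3 6.

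Across all 14338 loci, changes from 0.4% salt to HS_SCR and from HS_SCR to HS_DT ran in opposite directions. Of the 1175 genes that rose in HS_SCR, 1161 (98.8%) had a lower mean in HS_DT than in HS_SCR, and of the 699 that fell, 699 had a higher mean in HS_DT. These genes were chosen by their HS_SCR mean, which enters both changes, so their choice alone favours opposite signs. The correlation of the log2 changes across genes, which are not independent replicates, was -0.83, and 83.3% of loci had opposite signs. Both changes use the same HS_SCR libraries. Unchanged groups that share them already give a correlation of -0.54 (95% range -0.90 to 0.29 in 1000 simulations) and opposite signs at 70.1% of loci. The covariance was -0.155, outside the simulated range of -0.0943 to 0.00934 (median -0.0355). That simulation pooled the spread of all groups, whereas the spread of the 3 HS_SCR libraries alone gives -0.0587. The simulated range is therefore too narrow for HS_SCR as the shared group, and the covariance cannot be judged against it. Cldn7 was the 1 gene called in both. A scale from 0 at the 0.4% salt mean to 1 at the HS_SCR mean was set over the 1874 genes called between these groups. Genes were weighted by the size of that change, and they were chosen by the means that set the scale. The libraries labelled HS_DT lay at 0.449, 0.450 and 0.272 (mean 0.390 ± 0.102, SD). Without any effect that position is 0.5 only if the HS_SCR and 0.4% salt means are equally variable. The HS_SCR libraries varied more, which lowers it, so these positions do not tell an effect from none. The moderated F test over the 3 groups called 804 genes. It called 0 without 0.4% salt replicate 1 or 2 (2690 and 2546 at an unadjusted p under 0.05) and 195 without 0.4% salt replicate 3. Without HS_SCR replicates 2 and 3 it called 11 and 3860, and without HS_DT replicates 1, 2 and 3 it called 230, 3 and 442.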

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

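The proximal tubule covariate, the locus-width correction and the removal of the 2 libraries richest in proximal tubule markers were chosen after seeing the data. The other settings were chosen before. Pseudocounts of 0.1 and 0.5 FPKM, median-ratio rescaling and robust variance moderation left the counts and calls much as they were.

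With no filter on low values, HS_DT minus HS_SCR gave 3 genes and the F test 535, and Dnmt3a in HS_SCR minus 0.4% salt stayed at -0.70 with an adjusted p of 0.0573. With a mean FPKM of at least 5, HS_DT minus HS_SCR gave 154 genes and HS_DT minus 0.4% salt 2. Under quantile normalization HS_DT minus HS_SCR gave 0 genes by limma (2469 at an unadjusted p under 0.05) and the F test 515. With the replicate block it gave 0 (2889).

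With library weights the counts were 4019 genes in HS_SCR minus 0.4% salt, 1496 in HS_DT minus HS_SCR, 1805 in HS_DT minus 0.4% salt and 3934 by the F test, with 6 lists in HS_DT minus HS_SCR and a correlation of the opposite changes of -0.78. Tet3 was at -0.64 in HS_SCR minus 0.4% salt, Dnmt3a and Tet3 at 0.57 and 0.52 in HS_DT minus HS_SCR, and Dnmt3a at -0.32 in HS_DT minus 0.4% salt, all called. The median of oxidative phosphorylation turned to -0.0769 in HS_DT minus HS_SCR, and that of cholesterol synthesis to -0.0329 in HS_DT minus 0.4% salt.

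With the rat number series as a factor, Dnmt3a in HS_SCR minus 0.4% salt was at -0.43 (adjusted p = 0.112), HS_DT minus HS_SCR gave 422 genes, and the correlation was -0.79. In HS_DT minus 0.4% salt Tet3 turned to 0.00730, Bst1 to -0.0891, inflammatory genes to -0.115, interferon-stimulated genes to -0.0454 and the unfolded protein response to -0.0665.

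With the proximal tubule score as a covariate limma gave 0 genes in HS_SCR minus 0.4% salt (2154 at an unadjusted p under 0.05), 0 in HS_DT minus HS_SCR (1959) and 0 by the F test (1694), with 7 lists in HS_DT minus HS_SCR. In HS_SCR minus 0.4% salt Dnmt3a was at -0.77 (adjusted p = 0.274), PHLDA2 at 0.11 and Atp6v0a4 at 0.0460, with proximal tubule markers at 0.0474 and principal cell markers at 0.0846. Proximal tubule markers were at -0.28 in HS_DT minus HS_SCR. The score partly goes with the groups, so this fit loses precision, and it removes the mean change of the proximal tubule markers by construction. With the locus-width trend removed HS_DT minus HS_SCR gave 0 genes (2696).

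Without the 2 libraries richest in proximal tubule markers, limma gave 0 genes in HS_SCR minus 0.4% salt (3010), 0 in HS_DT minus HS_SCR (1612) and 0 by the F test (2188), with Dnmt3a at -0.74 (adjusted p = 0.141) and a correlation of -0.75. The fit with the 2 groups compared only gave 466 genes and Dnmt3a at -0.70 (adjusted p = 0.0892) in HS_SCR minus 0.4% salt, and 1 gene in HS_DT minus 0.4% salt. Lists numbered 0, 0 and 0 in the 3 comparisons with the inter-gene correlation estimated, and 7, 1 and 0 with fry.

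Leaving out each library in turn gave 347 to 5188 genes in HS_SCR minus 0.4% salt, 0 to 2300 in HS_DT minus HS_SCR, 0 to 6 in HS_DT minus 0.4% salt and 0 to 3860 by the F test. Lists numbered 9 to 18, 8 to 12 and 14 to 18. Dnmt3a ran from -0.91 to -0.53, from 0.20 to 0.57 and from -0.40 to -0.25 in the 3 comparisons, and Tet3 from -0.70 to -0.39, from 0.22 to 0.53 and from -0.22 to -0.14. The correlation ran from -0.86 to -0.73. In HS_DT minus HS_SCR the median of oxidative phosphorylation turned to -0.11 without HS_SCR replicate 3 and was 0.19 without HS_SCR replicate 1.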

Other observations

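Immediate early genes and p53 targets were higher in HS_SCR than in 0.4% salt by camera, and the other lists of this paragraph did not pass with all 9 libraries. Of the immediate early genes, Myc (1.16 ± 0.14), Ier3 (0.98 ± 0.16) and Jund (0.67 ± 0.12) rose in HS_SCR, and the list of 17 had a median of 0.44 (camera adjusted p = 0.0240; adjusted p = 0.725 with an estimated correlation). That call ended without 0.4% salt replicate 3 (median 0.39, 0.0584), HS_SCR replicate 2 (median 0.16, 0.136) or HS_SCR replicate 3 (median 0.50, 0.176). It also ended at a minimum mean of 5 FPKM (median 0.45, 0.0580), with library weights (median 0.54, 0.0862), with the rat number series as a factor (median 0.35, 0.101) and with the locus-width trend removed (median 0.31, 0.0883). Hspb1, a chaperone of the tonicity-responsive list, rose from 65.8 ± 0.938 to 157 ± 23.1 FPKM and the water channel Aqp1 fell by -0.69 ± 0.19, and that list did not pass (median -0.09, camera adjusted p = 0.590). Of the targets of the hypoxia-inducible factor, Ldha (0.64 ± 0.14), Ankrd37 (0.81 ± 0.20) and Kdm3a (0.43 ± 0.11) rose, and the list did not pass (median 0.17, camera adjusted p = 0.123). Bbc3, a p53 target that promotes cell death, rose (0.73 ± 0.08), and the p53 list had a median of 0.21 (camera adjusted p = 0.0337; adjusted p = 0.521 with an estimated correlation). The p53 call ended without HS_SCR replicate 3 (median 0.21, 0.234), with library weights (median 0.17, 0.129), with the proximal tubule score as a covariate (median 0.24, 0.108) and with the locus-width trend removed (median 0.18, 0.110). Atf4 of the unfolded protein response rose (0.54 ± 0.14), not when adjusted over its list alone, and the list did not pass (median 0.21, camera adjusted p = 0.0867). It passed without HS_SCR replicate 3 (median 0.35, 0.00104), with library weights (median 0.28, 0.0106), with no filter on low values (median 0.24, 0.0146), without HS_DT replicate 2 (median 0.21, 0.0442) and in the fit of the 2 groups alone (median 0.21, 0.0493). Clock fell (-1.06 ± 0.29), not when adjusted over its list alone, and Nfil3 rose (0.93 ± 0.18), and circadian genes did not shift as a list (median 0.03, camera adjusted p = 0.887).

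Cholesterol synthesis genes were lower in HS_SCR than in 0.4% salt (median -0.33, camera adjusted p = 0.00253; adjusted p = 0.682 with an estimated correlation), with falls of Fdft1 (-0.83 ± 0.18) and Stard4 (-0.61 ± 0.11) and a rise of Pmvk (0.71 ± 0.10). Without 0.4% salt replicate 1 the cholesterol median was -0.21 (camera adjusted p = 0.0344). Cell cycle genes were lower (median -0.31, camera adjusted p = 0.00388; adjusted p = 0.725 with an estimated correlation), and Tyms, of thymidylate synthesis, fell (-0.70 ± 0.12). Interferon-stimulated genes were lower (median -0.26, camera adjusted p = 0.0286; adjusted p = 0.753 with an estimated correlation), with a fall of Ifih1 (-0.49 ± 0.11) and a rise of Isg20 (0.48 ± 0.10). Without HS_SCR replicate 3 the calls of cholesterol synthesis (median -0.31, 0.0593), cell cycle (median -0.07, 0.479) and interferon-stimulated genes (median -0.10, 0.675) ended. The cell cycle call also ended without 0.4% salt replicate 3 (median -0.20, 0.0584) and with library weights (median -0.14, 0.113). The interferon call also ended without 0.4% salt replicate 3 (median -0.26, 0.0680) or HS_SCR replicate 2 (median -0.18, 0.104), with no filter on low values (median -0.25, 0.0560) and with library weights (median -0.20, 0.172). Without HS_SCR replicate 1 the interferon median moved further from that of 0.4% salt, to -0.48 (camera adjusted p = 1.2e-07). From HS_SCR to HS_DT, Cry1 (-0.79 ± 0.15) and Per1 (-0.99 ± 0.33) of the clock were lower without passing, and the list did not pass (median -0.15, camera adjusted p = 0.309).

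From 0.4% salt to HS_DT, immediate early genes (median 0.34, camera adjusted p = 0.000724; adjusted p = 0.524 with an estimated correlation) and p53 targets (0.17, camera adjusted p = 0.00436; adjusted p = 0.430 with an estimated correlation) were higher. So were the unfolded protein response (0.19, camera adjusted p = 0.0412; adjusted p = 0.633 with an estimated correlation), interferon-stimulated genes (0.16, camera adjusted p = 0.0455; adjusted p = 0.780 with an estimated correlation) and pericyte markers (0.09, camera adjusted p = 0.0442; adjusted p = 0.432 with an estimated correlation). Cholesterol synthesis had a median of 0.17 there (camera adjusted p = 0.0396; adjusted p = 0.759 with an estimated correlation). Of these 6 lists, the p53 targets alone kept the call in all settings of the fit. The immediate early call ended without HS_DT replicate 2 (median 0.04, 0.0728) and with the rat number series as a factor (median 0.16, 0.0716). With that factor the medians of the unfolded protein response (-0.07, adjusted p = 0.645) and interferon-stimulated genes (-0.05, 0.943) turned. The unfolded protein call also ended without HS_DT replicate 2 (median 0.09, 0.203), 0.4% salt replicate 1 (median 0.13, 0.0791) or 0.4% salt replicate 3 (median 0.16, 0.0799), and the interferon call without HS_DT replicate 3 (median 0.11, 0.324), HS_DT replicate 1 (median 0.12, 0.0590), 0.4% salt replicate 1 (median 0.14, 0.112) or 0.4% salt replicate 3 (median 0.16, 0.0615). At a minimum mean of 5 FPKM, with the proximal tubule score as a covariate and with the locus-width trend removed, the unfolded protein call ended (medians 0.19, 0.16 and 0.14, adjusted p = 0.0724, 0.0807 and 0.0678), as did the interferon call (medians 0.16, 0.10 and 0.13, adjusted p = 0.0724, 0.274 and 0.0678). The interferon call ended as well with library weights (median 0.07, 0.214) and without the 2 libraries richest in proximal tubule markers (median 0.11, 0.290). The pericyte call ended without each library except 0.4% salt replicate 3, with adjusted p from 0.0533 to 0.268. It also ended in 7 other settings, with adjusted p from 0.0717 with the replicate block to 0.305 at a minimum mean of 5 FPKM, and its median was 0.04 to 0.17 in the fits without the call. Without 0.4% salt replicate 3 the pericyte median was 0.23 (camera adjusted p = 0.00101). With library weights the median of cholesterol synthesis turned (-0.03, 0.819). Its call ended without 0.4% salt replicates 2 (median 0.13, 0.0673) and 3 (median 0.10, 0.527), HS_SCR replicate 3 (median 0.17, 0.105) or HS_DT replicates 1 (median 0.09, 0.270) and 3 (median 0.14, 0.155). It also ended with the rat number series as a factor (median 0.08, 0.211), the proximal tubule covariate (median 0.06, 0.454), the locus-width trend removed (median 0.17, 0.0678), the 2 libraries richest in proximal tubule markers left out (median 0.12, 0.246) and the fit of the 2 groups alone (median 0.17, 0.0573).

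Of the tests that follow, the comparison of the proximal tubule markers with their common median was written after the result was seen, and the others before.

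The first pattern is that Dnmt3a and Tet3 were not lower in the libraries labelled HS_DT than in those labelled HS_SCR. Removing the gene-width trend between libraries left the Dnmt3a change at 0.30 ± 0.15 and that of Tet3 at 0.28 ± 0.13. Adjusting for proximal tubule content left them at 0.41 ± 0.23 and 0.38 ± 0.20. Each stayed above 0 by more than its SE, the mark set beforehand, so neither step turned the direction. None passed by limma (adjusted p from 0.272 to 0.493), and the proximal tubule score partly goes with the groups. These fits therefore cannot exclude either explanation. The libraries may carry exchanged group labels, or a reduction by the GapmeRs could have faded before collection. Neither was tested, since no marker other than Dnmt3a and Tet3 tells HS_SCR from HS_DT. A measurement of Dnmt3a and Tet3 protein in the same kidneys, not held here, would bear on both. It need not separate them, since a reduction that had faded in RNA could still be present in protein.

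The second pattern is that proximal tubule markers were lower in HS_SCR than in 0.4% salt. A smaller share of proximal tubule in the dissected tissue asks for a similar fall of all markers, and of 16 markers with a mean of at least 10 FPKM, 2 (Napsa and Ass1) had a 95% interval that excludes the median of -2.80. The changes ran from -0.21 to -4.43 and the intervals reached 1.94 (median) to either side, too wide for the count to tell a smaller share from other changes of these genes. With the gene-width trend removed the median of the list stayed at -2.73, and that trend does not account for it. A loss of proximal tubule through the treatment was not tested, and the median of the thick ascending limb markers stayed at -0.79 when proximal tubule content was adjusted for.

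The third pattern is that ribosomal protein genes were higher in HS_SCR. With the gene-width trend removed the median was 0.52, and with proximal tubule content adjusted for it was 0.61, so most of the rise remained after each. Among 10000 random lists matched in expression and locus width the medians had a median of 0.27 and a highest value of 0.60, against 0.65 for the ribosomal proteins. Genes of like expression and width thus rose as well, by less. The random lists were drawn gene by gene and do not hold genes that vary together. Growth of the tubular cells on the high-salt diet might raise these transcripts, and that was not tested here.

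Exchanging libraries between 2 groups gives 10 splits, which are too few to exclude a chance origin. For genes, the real count of 1874 in HS_SCR minus 0.4% salt was reached in 1 of 10 splits (highest other 1), that of 1 in HS_DT minus HS_SCR in 4 of 10 (highest other 2) and that of 0 in HS_DT minus 0.4% salt in 10 of 10 (highest other 1). For lists, the real count of 17 was reached in 1 of 10 (highest other 14), that of 11 in 4 of 10 (highest other 17) and that of 18 in 1 of 10 (highest other 16). List counts with the preset correlation are therefore high in exchanged groups as well. The F test over the 3 groups called 804 genes, and 1 of 100 groupings, the real one, reached that count (highest other 4).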
